A study of Nothobranchius furzeri with 20 samples.

How the data were processed

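The 20 libraries were made from total RNA of skin of male killifish of the strain MZM-04/10p with the TruSeq RNA kit, version 2, per the labels' protocols. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build, the gene annotation, the treatment of strand and that of reads matching several places are not given in the sources used here. Genes that overlap or have close copies, and sense and antisense partners, may therefore share reads. The deposited counts are whole numbers of reads per gene and library with no normalization. The deposited RPKM values hold reads scaled by gene length and library total, with lengths and totals chosen by the authors.

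The deposited RPKM table was compared with the counts. For 10228 genes with at least 100 counts and an RPKM of at least 1 in every library, count divided by RPKM was not proportional to the library's own total (median SD of the natural log ratio over libraries 0.227). By this measure 0% of genes were constant to within an SD of 0.001. It was constant in 100% of these genes once the 20 library totals were recycled down the rows of the table (median SD 3.77e-05). In this arrangement 5.00% of values are divided by their own library's total, and totals differ by up to 1.87-fold, so the deposited RPKM values carry an added error between libraries. All main results therefore use the counts. The same ratio gave the gene length behind the table, in kb, for 22884 genes and for 100% of tested genes, with a median of 2.38 kb.

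Groups were taken from the age and perturbation labels. Replicates 1 to 5 of 27 weeks have titles JM132 to JM136 and replicates 6 to 10 have titles JM140 to JM144, and this division was fixed from the titles before the data were examined. It names no condition. Replicate numbers follow the order of the samples and pair no fish across groups. No 2 libraries of a set agreed within sampling noise: over 40 pairs the lowest chi-square per degree of freedom was 34.3, so every library was counted once. No per-sample column was left unused.

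Differences were tested on the counts with edgeR 4.0.16 (R 4.3.3): TMM scaling, its expression filter by group, robust quasi-likelihood fits and Benjamini-Hochberg adjustment with a threshold of 0.05, with only the compared groups in each fit. A standard error is the absolute log2 fold change divided by the square root of F. A fold change is that of the fit, and CPM values are TMM-scaled over all 20 libraries. Log2 CPM used a prior count of 2. Library measures were compared with exact two-sided permutation tests of the difference of means, adjusted over 5 measures. With 5 against 5 libraries the smallest p is 0.00794. Totals were 20597690 to 38619614 counts, so a gene at 1 CPM before TMM scaling has about 20.6 to 38.6 counts in a library. For TMM-scaled CPM the counts also change with each library's scaling factor.

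The test was checked on simulated counts with 200 changed genes. Genes were drawn independently, with no structure between fish, so the shares below need not hold in the real data. In the design of 5 against 5 fish of 9 weeks (18326 genes), 10% of 1.5-fold, 36% of 2-fold, 82% of 4-fold and 96% of 8-fold changes were called, with 6 false among 118 calls. In the design of age (18661 genes) the shares were 8%, 50%, 86% and 92%, with 7 false among 125 calls, and in that of the title runs (18104 genes) 10%, 40%, 84% and 96%, with 8 false among 123.

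The rule for named genes, fixed before the data were examined, took genes with a symbol, an adjusted p under 0.05 and a mean of at least 1 CPM, by largest change in each direction, or by smallest adjusted p for the title runs. The files hold identifiers alone, and 0 of 26739 matched the reference gene table of the assembly NfurGRZ-RIMD1. For this reason up to 2 identifiers per direction with the largest change, past the threshold and at a mean of at least 1 CPM, are given for each comparison, also for the title runs. None is given a name or function. The gene list tests, cell type markers and shares of muscle, haemoglobin and ribosomal transcripts that had been fixed need names and were not run, nor was the muscle marker covariate.

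Alternatives were DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1), the last on log2(RPKM + 0.1) and log2(RPKM + 1) with a mean RPKM of at least 0.5 or no filter. Others were DESeq2's size factors in edgeR, no count filter, a filter of 1 CPM in 5 libraries, 1 surrogate variable (sva 3.50.0), all 20 libraries in 1 fit, other reference groups, single title runs and leaving out each fish. RPKM with own totals, title runs as groups of their own, a covariate for fish-to-fish variation, removal of the length trend, thinning to the smallest total, further checks of the genes shared by both runs, leaving out unexercised fish for 1 named gene and DESeq2 on other splits were added after the data were seen. The covariate is the first component of the differences between fish inside the 2 title runs of 27 weeks, applied to every library, and is called the fish-to-fish axis.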

Results

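Skin RNA was sequenced from male turquoise killifish (Nothobranchius furzeri), a short-lived annual fish used to study ageing, of the strain MZM-04/10p. The 20 libraries fell into 3 labelled groups. There were 5 from fish of 9 weeks without exercise, 5 from fish of 9 weeks exercised in a swim tunnel and 10 from exercised fish of 27 weeks. A swim tunnel is a chamber in which fish swim against a current. The labels name no unexercised group of 27 weeks, so exercise was not compared at that age. The sample titles of the 27-week fish carry consecutive numbers in 2 separate runs, here replicates 1 to 5 and replicates 6 to 10, under 1 shared label. Each library was taken as 1 fish. The labels do not say that they came from separate animals, so p-values measure the spread between these samples.

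Counted reads totalled 20597690 to 38619614 per library. The mean total was 31449785 ± 4277112 (SD, n = 5) in unexercised fish of 9 weeks, 31029591 ± 3884886 (SD, n = 5) in exercised fish of 9 weeks and 30128953 ± 5367380 (SD, n = 10) in exercised fish of 27 weeks. Of 26739 genes in the table, 3855 had no count in any library. The files pair no gene identifier with a gene name, so at most 2 identifiers per direction are given for each comparison. Gene groups are described by size of change, by gene length and by the libraries in which they changed.

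The first principal component of log2 CPM, that is counts scaled by library total, held 29.02% of the variance and ordered the libraries by age and, at 27 weeks, by title run. Libraries of 9 weeks lay between -56.3 and -22.4 on it, replicates 6 to 10 of 27 weeks between -9.10 and 4.90, and replicates 1 to 5 between 71.7 and 90.4. The second component held 23.4% of the variance and spread the fish inside each labelled group, from -91.4 to 38.3 in unexercised fish of 9 weeks and from -38.5 to 49.7 in exercised fish of that age.

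**Figure D1:**
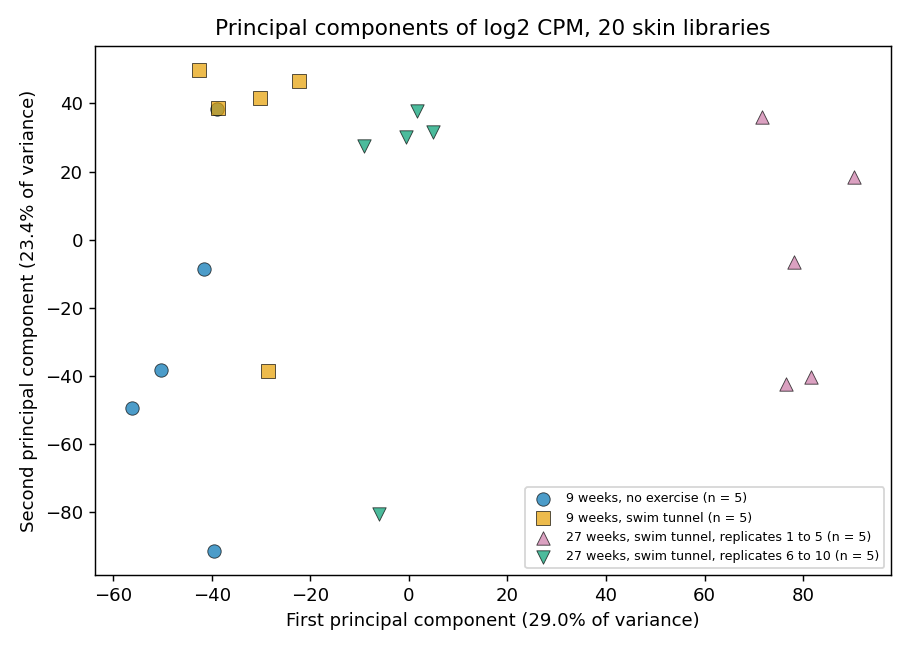
Each point is 1 library, placed by its first (29.02% of variance) and second (23.4%) principal component of log2 CPM, with colour and shape for the group and, at 27 weeks, the title run. Replicates 1 to 5 of 27 weeks lie between 71.7 and 90.4 on the first component, apart from the other 15 libraries, and the second component spreads fish within groups. One point of each 9-week group overlaps near -39 on the first component.

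The first comparison asked which genes of the skin differed between exercised and unexercised young fish. Each group is 1 run of title numbers, so exercise and anything that goes with those numbers cannot be told apart. A pair of identifiers passed the threshold. Nfu_g_1_008319 rose 1.8-fold, from 15.7 ± 2.33 CPM (SD, n = 5) without exercise to 28.7 ± 2.26 CPM (SD, n = 5) with it. It was above all unexercised fish in 5 of 5 exercised fish. Nfu_g_1_013151 fell from 73.2 ± 4.81 CPM (SD, n = 5) to 42.3 ± 3.39 CPM (SD, n = 5), 1.77-fold lower. It was below all unexercised fish in 5 of 5 exercised fish. In the 27-week fish, all labelled as exercised, the mean of Nfu_g_1_008319 was 49.7 ± 6.49 CPM (SD, n = 5) in replicates 1 to 5 and 13.2 ± 4.22 CPM (SD, n = 5) in replicates 6 to 10. That of Nfu_g_1_013151 was 23.2 ± 6.27 and 98.1 ± 11.05 CPM (SD, n = 5 each).

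In edgeR's quasi-likelihood test the log2 fold change of Nfu_g_1_008319 was 0.85 (SE 0.0973, adjusted p = 0.0336) and that of Nfu_g_1_013151 was -0.82 (SE 0.0862, adjusted p = 0.0288). These were 2 of 18520 genes tested. An unadjusted p under 0.05 was found for 2739 genes, where chance gives 926. The 5 fish of one group lay wholly above or below those of the other for 557 genes, 3.01% against 0.794% by chance. Neither count was set against other splits of the fish, and genes are not independent, so neither excess shows an effect of exercise. DESeq2 called 487 genes (252 higher and 235 lower), among them both named genes. Over 30 DESeq2 splits of the same fish, the highest other gave 418 genes and the median of the others was 7. The edgeR fits of all 20 samples and with a surrogate variable called 0, at unadjusted p under 0.05 in 1688 and 2308 genes. Leaving out 1 fish ended every call for 7 of the 10 fish and gave 7 calls without replicate 1 of the exercised group. No library measure passed a test between these groups. The exact permutation p (two-sided, n = 5 against 5) was 0.881 for total counts, 0.206 for genes at 1 CPM or more, 0.357 for the share of counts in the 10 highest genes, 0.524 for the scaling factor and 0.119 for the trend on gene length, with adjusted p of 0.516 to 0.881 over the 5 measures.

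The second comparison asked how the skin of exercised fish differed with age. Each age has title runs of its own, so age and anything that goes with the title numbers cannot be told apart. The pooled fit took the 27-week fish as 1 group, although their title runs differed from each other in 7613 genes. Of 18801 genes tested, 4609 differed between 27 and 9 weeks, 2487 higher and 2122 lower in the older fish. Among them 1518 differed by more than 2-fold, 1096 higher and 422 lower, and 190 by more than 4-fold, 164 higher and 26 lower. This excess of large increases was smaller when each title run was set against the same 9-week fish. In replicates 1 to 5, 2019 genes were higher and 1640 lower by more than 2-fold, and 438 and 193 by more than 4-fold. In replicates 6 to 10 these were 458 and 224, and 44 and 32. Nfu_g_1_001702 and Nfu_g_1_001750 had the steepest falls among called genes with a mean of at least 1 CPM. The first fell from 9.23 ± 4.06 CPM (SD, n = 5) at 9 weeks to 0.685 ± 0.748 CPM (SD, n = 10) at 27 weeks, 13.6-fold lower. The second fell from 13.1 ± 5.64 to 0.987 ± 1.11 CPM (SD, n = 5 and 10), 13.4-fold lower. Both were below every exercised 9-week fish in 10 of 10 older fish. Unexercised fish of 9 weeks had 8.36 ± 2.76 and 11.1 ± 2.80 CPM (SD, n = 5).

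The log2 fold change was -3.77 for Nfu_g_1_001702 (SE 0.763, adjusted p = 0.00541) and -3.74 for Nfu_g_1_001750 (SE 0.855, adjusted p = 0.00876) in edgeR's test. Both fell furthest in replicates 1 to 5, to 0 to 5 and 0 to 7 counts per library, against 18 to 52 and 29 to 69 counts in replicates 6 to 10. Nfu_g_1_013789 rose from 0.0550 ± 0.0885 CPM (SD, n = 5) to 1.83 ± 2.55 CPM (SD, n = 10), a log2 fold change of 5.02 (SE 1.22, edgeR adjusted p = 0.0113). It was above every exercised 9-week fish in 10 of 10 older fish. Its counts were 0 to 6 in exercised fish of 9 weeks, 0 in 3 of the 5, and without replicate 1 of them the log2 fold change was 6.50. Replicates 2 and 7 of 27 weeks had 6.66 and 6.62 CPM and the other 8 had 0.243 to 1.05 CPM. Nfu_g_1_010568, the other identifier named by the rule, had 0.210 ± 0.102 CPM (SD, n = 5) at 9 weeks and 12.1 ± 33.9 CPM (SD, n = 10) at 27 weeks. It had an edgeR log2 fold change of 5.84 (SE 1.98, adjusted p = 0.0421). This call ended when any 1 of the 5 exercised 9-week fish was left out (adjusted p = 0.0725 to 0.0936) and without replicate 2 of 27 weeks (0.0504). It did not pass in limma-voom (adjusted p = 0.278) or the fit of all 20 samples (0.0613) and passed in DESeq2 (0.00686). Its mean rested on single fish, with 108.5 CPM in replicate 7 of 27 weeks (log2 fold change 2.66 without it) and medians of 0.466 CPM at 27 weeks and 0.179 CPM at 9 weeks. Against unexercised fish of 9 weeks, with a median of 1.21 CPM and 225.2 CPM in replicate 3, its log2 fold change was -1.95 (SE 1.63, adjusted p = 0.384), and 3.30 (SE 1.93, adjusted p = 0.224) without that fish.

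Both title runs were compared with the exercised 9-week fish separately. Replicates 1 to 5 differed in 9238 of 18348 genes (4746 higher and 4492 lower) and replicates 6 to 10 in 2927 of 18234 genes (1536 higher and 1391 lower). Of the 4609 genes called in the pooled comparison, 1933 (41.9%) were called in the same direction in both runs, 2384 in replicates 1 to 5 alone, 223 in replicates 6 to 10 alone and 69 in neither. Of the same 4609 genes, 2510 (54.5%) also differed between the runs, against 7613 of all 18306 genes tested between them (41.6%). Over all genes tested in both runs, 960 were higher and 992 lower in both, where independent lists of these lengths would share 392 and 345. Together these are 1952 genes, and 1239 were shared without replicate 4 of the exercised 9-week fish and 1315 to 1670 without any other of them. Another 97 were called in opposite directions. Both runs were set against the same 9-week fish, which can itself add shared calls. Simulated unchanged groups shared 0 genes on average. This cannot measure that addition, since unchanged groups give few calls to share. With a separate 9-week group for each run, 1552 genes were called in both in the same direction (684 higher and 868 lower, 343 and 318 for independent lists). With the 9-week groups exchanged there were 1666 (899 and 767, against 422 and 315). The numbers for independent lists take every gene as equally likely to be called, which was not checked.

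Fewer genes were called for age when 1 exercised 9-week fish was left out, with 2467 calls without replicate 4, 2747 without replicate 5 and 2813 without replicate 3. The share of calls that were higher was 54.0% in the main test and 55.4% with DESeq2's size factors (2551 higher and 2057 lower). It was 44.4% with limma-voom (1957 higher and 2452 lower). It was 32.5% with limma-trend on RPKM, which also divides by gene length, recomputed with each library's own total (1136 higher and 2355 lower), where unit, test and filter differ together.

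**Figure D2:**
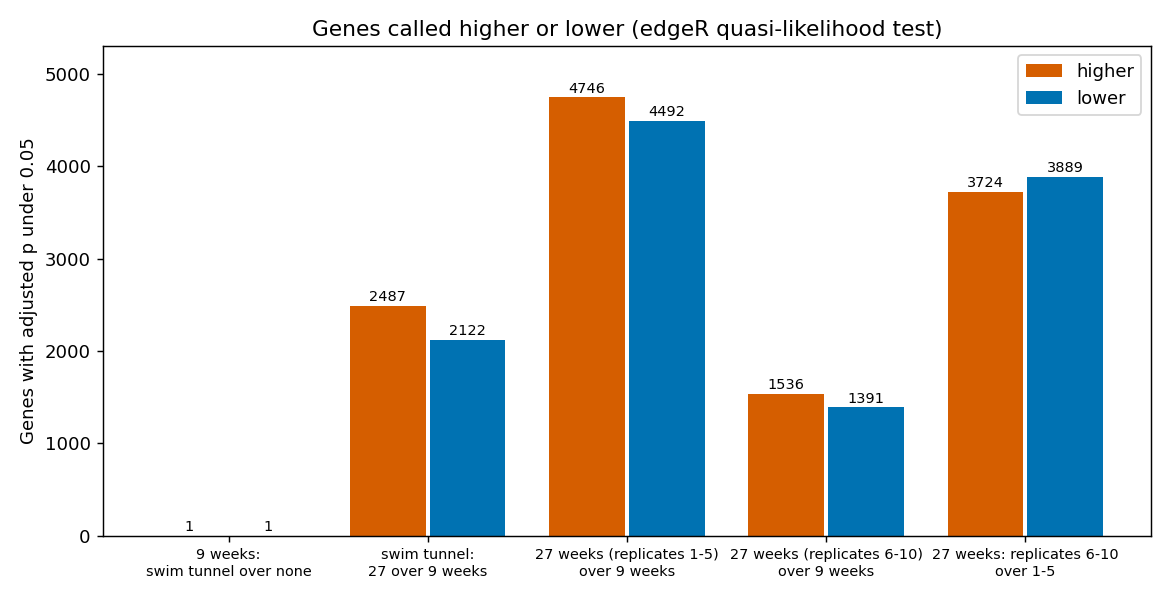
Bars give the number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test that were higher or lower in the first-named set of each comparison. Exercise at 9 weeks gave 1 higher and 1 lower gene, age in exercised fish 2487 and 2122, and the 2 title runs of 27 weeks differed from each other in 3724 and 3889.

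On average, long genes were lower relative to short genes in older fish, most of all in replicates 1 to 5. The slope of log2 CPM, relative to each gene's mean over all libraries, on log2 gene length averaged 0.0238 ± 0.0115 (SD, n = 5) in exercised fish of 9 weeks and -0.0189 ± 0.0235 (SD, n = 10) in those of 27 weeks (exact permutation test, two-sided, p = 0.00233, adjusted p = 0.0117 over 5 library measures). Unexercised fish of 9 weeks averaged 0.0140 ± 0.00472 (SD, n = 5). Within the title runs it was -0.0373 ± 0.0163 in replicates 1 to 5 (n = 5, exact p = 0.00794, the smallest possible, adjusted p = 0.0397) and -0.000452 ± 0.0111 in replicates 6 to 10 (n = 5, exact p = 0.0159, adjusted p = 0.0794), so the lower slope of replicates 6 to 10 did not pass the correction. Among the longest 25% of tested genes (median 6.48 kb), 404 were called higher and 661 lower with age. Among the shortest 25% (median 0.801 kb), 764 were higher and 417 lower. Gene lengths were those behind the deposited RPKM values. The other 4 measures did not pass, with exact p of 0.741 to 0.951 (n = 5 against 10).

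The third comparison, within 1 label, set replicates 6 to 10 of the 27-week fish against replicates 1 to 5. It found 7613 of 18306 genes, 3724 higher and 3889 lower in replicates 6 to 10, and 2379 by more than 2-fold. The fish of one run lay wholly above or below those of the other for 5578 genes, 30.5% against 0.794% by chance. Nfu_g_1_015122 was lower in replicates 6 to 10, at 0.713 ± 0.460 CPM against 11.2 ± 2.80 CPM (SD, n = 5 each), with a log2 fold change of -3.96 (SE 0.414, edgeR adjusted p = 4.31e-05). Its level was 0.465 ± 0.179 CPM in exercised and 0.380 ± 0.112 CPM in unexercised fish of 9 weeks (SD, n = 5 each). Nfu_g_1_002589 was lower as well, at 0.295 ± 0.0671 against 3.86 ± 1.88 CPM (SD, n = 5 each), with a log2 fold change of -3.68 (SE 0.417, edgeR adjusted p = 6.85e-05).

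Among called genes with a mean of at least 1 CPM, Nfu_g_1_001498 and Nfu_g_1_004238 had the largest positive changes in replicates 6 to 10 over replicates 1 to 5. Both rested on 2 fish. Nfu_g_1_001498 had 101.5 CPM in replicate 6 and 74.9 CPM in replicate 7, against at most 0.832 CPM in the other 3 fish of that run. Replicates 1 to 5 had 0.648 ± 0.248 CPM (SD, n = 5), a log2 fold change of 5.78 (SE 1.59, edgeR adjusted p = 0.0140). Nfu_g_1_004238 had 32.8 and 23.4 CPM in the same pair of fish and 0.296 ± 0.0961 CPM (SD, n = 5) in replicates 1 to 5, with a log2 fold change of 5.29 (SE 1.58, edgeR adjusted p = 0.0205). Without replicate 6 the log2 fold changes were 4.91 and 4.39. The 2 genes called for exercise at 9 weeks differed between the runs too. The log2 fold change of replicates 6 to 10 over replicates 1 to 5 was -1.91 for Nfu_g_1_008319 (SE 0.213, edgeR adjusted p = 6.27e-05) and 2.08 for Nfu_g_1_013151 (SE 0.178, adjusted p = 1.30e-05).

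Each of the 10 libraries correlated better, on average, with its own run than with the other, by 0.0202 to 0.0342 in Pearson's r across genes, which are not independent replicates. The scaling factor averaged 1.07 ± 0.0833 in replicates 1 to 5 and 0.899 ± 0.0562 in replicates 6 to 10 (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0198). The length slope differed as well (n = 5 against 5, exact p = 0.00794, adjusted p = 0.0198). Total counts, genes at 1 CPM or more and the share of the 10 highest genes did not pass, with exact p of 0.230 to 0.452 (n = 5 against 5).

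**Figure D3:**
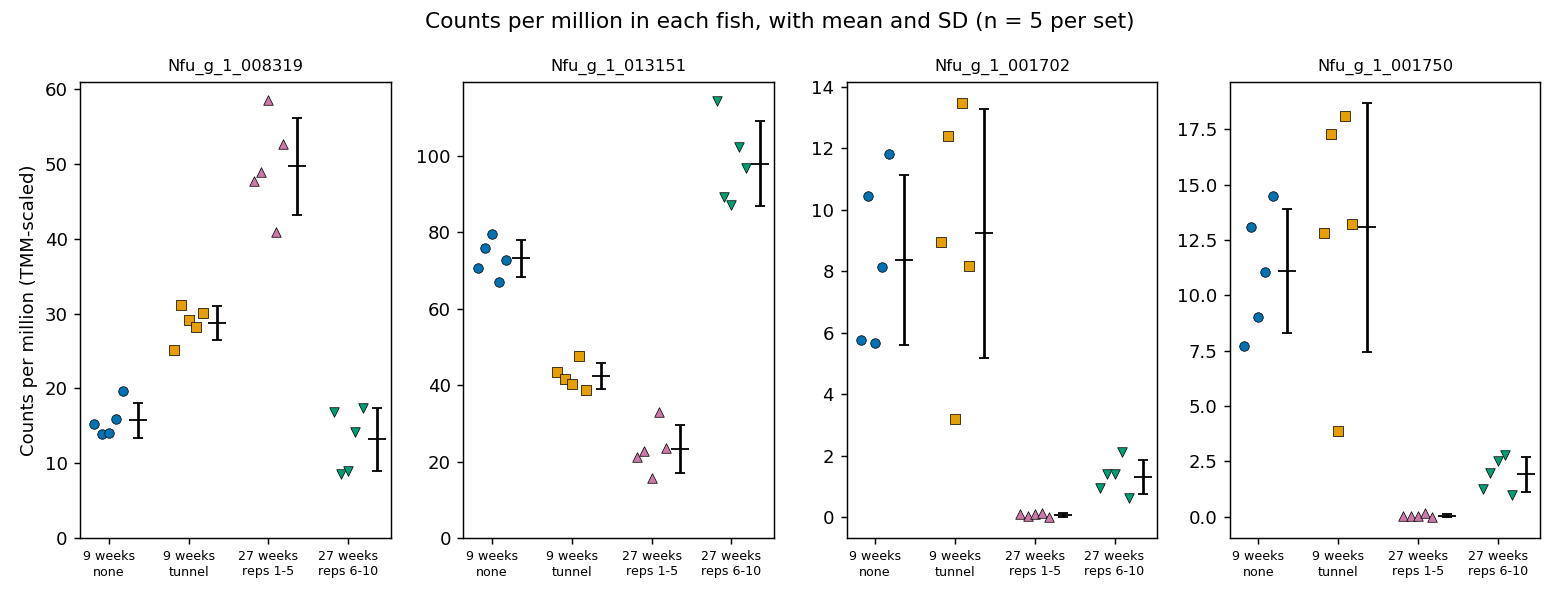
Points give TMM-scaled CPM of 4 genes in each fish, and the bars beside them the mean and SD of each set (n = 5), with a vertical scale of its own in each panel. Nfu_g_1_008319 averaged 15.7, 28.7, 49.7 and 13.2 CPM and Nfu_g_1_013151 73.2, 42.3, 23.2 and 98.1 CPM across the 4 sets from left to right, while Nfu_g_1_001702 and Nfu_g_1_001750 were lower in both runs of 27 weeks than at 9 weeks.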

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

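The split test of the title runs, the test of a wrong age label and that of a batch were chosen after the difference between the runs was seen.

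A test of the difference found 7613 genes between the 2 title runs of the 27-week fish, which share 1 label. Grouping by chance was excluded: 1 of 100 splits of the 10 fish, the real one, gave as many genes, and the highest other gave 78. Depth and gene length as whole causes were argued against, since 93.7% of the genes stayed called in the same direction with every library thinned to the smallest total and 94.5% after each library's trend on length was removed. Young fish under a wrong age label stay open for replicates 6 to 10: they differed from exercised 9-week fish in 2927 genes, where the highest split of the 9-week fish gave 331, but their mean Pearson's r across genes was 0.949 with exercised and 0.935 with unexercised 9-week fish and 0.925 with replicates 1 to 5. A batch and an unlabelled difference in treatment, housing or parentage cannot be told apart, as all 10 libraries were closer to their own run and the labels give nothing that crosses the runs, and no biological explanation was tested.

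Single-fish values in 4 cases stood far from the rest of their group, out of 48 checks in groups of 5 or 10, where chance gives about 2.4. Replicate 1 of the exercised 9-week fish lay at -38.5 on the second principal component, and the nearest other fish of its group at 38.7. The same fish had the one high value of Nfu_g_1_004238 in its group, 1.92 on the log2(CPM + 0.1) scale against -2.30 for the next. Replicate 3 of that group had the lowest Nfu_g_1_001750, 2.00 on that scale against 3.69 for the next. Replicate 7 of the 27-week fish had 6.76 on that scale for Nfu_g_1_010568, against 2.74 for the next.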

How the results depend on the processing

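The own-total RPKM, run-group, axis, unexercised left-out, length, thinning, DESeq2-split and shared-gene settings were chosen after the data were seen. Gene list tests and the muscle covariate were not run, for want of gene names. No paired analysis was possible because the labels carry no shared replicate numbers.

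For exercise at 9 weeks, against 2 genes, DESeq2 called 487, RPKM with own totals 11 and all samples with the runs as groups 5, while deposited RPKM called 0 in its 3 forms (1548, 1514 and 2018 genes at unadjusted p under 0.05), 1 surrogate variable 0 and all samples in 1 fit 0. The cause was not tested, except that DESeq2 on 30 splits of the 10 fish gave 487 for the real one, at most 418 for the others and 7 as their median. Leaving out each fish gave 0 to 7 genes: 0 without unexercised replicate 1, 2 or 4 or exercised replicate 2, 3, 4 or 5, 1 without unexercised replicate 3 and 7 without exercised replicate 1. Both named genes kept their direction in all 25 settings run, but often lost their calls. Nfu_g_1_008319 did not pass in 8 of 15 settings and 8 of 10 left-out fits. Nfu_g_1_013151 did not pass in 6 of 15 and 7 of 10. Adjusted p ran from 8.09e-11 to 0.622 for Nfu_g_1_008319 and 2.33e-15 to 0.639 for Nfu_g_1_013151 outside the left-out fits. In those fits it ran from 0.0205 to 0.164 and from 0.0264 to 0.164.

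For age, against 4609 genes, deposited RPKM called 1053 (pseudocount 0.1), 1070 (pseudocount 1) and 919 (no filter), the misplaced totals being part of these values. Replicates 1 to 5 alone gave 9238, replicates 6 to 10 alone 2927, both 9-week groups as reference 7856 and the runs as groups 7633, and 12 other settings stayed within 1.5-fold. The cause of these differences was not tested. Leaving out each fish gave 2467 (exercised 9-week replicate 4) to 5333 (27-week replicate 8), with 2813 and 2747 without exercised 9-week replicates 3 and 5. Nfu_g_1_010568 turned to -1.95 against unexercised and -1.01 against both 9-week groups. Without unexercised replicate 3 (225.2 CPM) these were 3.30 (adjusted p = 0.224) and 4.18 (0.0147), and without any other unexercised fish they stayed negative. It lost its call in 7 other settings and without exercised 9-week replicate 1, 2, 3, 4 or 5 or 27-week replicate 2 (adjusted p 0.0504 to 0.0936). Nfu_g_1_001702 and Nfu_g_1_001750 passed in all 34 settings run and Nfu_g_1_013789 in 30 of 31 (adjusted p 0.128 with pseudocount 1). The title runs gave 7332 to 8242 genes, and 6768 to 7673 with a fish left out. Genes shared by both runs numbered 1952, 1552 to 2667 in other settings and 1239 to 1670 with a 9-week fish left out (1239 without replicate 4). With 5 fish a group, 36% of simulated 2-fold changes were called.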

Other observations

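The tests of recycled totals, of the direction of the 2 contrasts over all genes and over 100 genes, of splits by whole title runs and of splits with the fish-to-fish axis were chosen after the values were seen.

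Of the 4609 age genes, 989 were called in both title runs and not called between the runs, 408 higher and 581 lower at 27 weeks. A missing call does not show equal levels, since 40% of simulated 2-fold changes were called in the design of the title runs. Genes called higher with age differed between the runs more often than those called lower, 64.1% against 43.1%, a difference that was not tested. Of all genes tested between the runs, 41.6% were called, near the share of the genes lower with age.

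The hypothesis that the runs share changes with age was tested with a separate 9-week group for each run. The genes called in both in the same direction were at least 1.99 times as many as independent lists would share in each direction and in either assignment of the groups. That ratio takes every gene as equally likely to be called, which was not checked, so it does not by itself show shared changes with age. For the 4609 age calls, 1 of 100 drawn splits of the 15 fish, the real one, gave as many. Such splits take the fish as exchangeable, which the title runs go against, so they do not exclude chance. The highest other gave 3281 and set replicates 1, 2, 3, 4 and 10 of 27 weeks against the rest. The fish are structured by title run, and splits by 1 whole run number 3, too few for a share under 0.05: the split by age gave 4609 genes, replicates 1 to 5 against the other 10 fish 8990 and replicates 6 to 10 against the other 10 fish 488, so 2 of 3 gave at least 4609. Every age also has title runs of its own, so age and anything that goes with the title numbers cannot be told apart. The 2 title runs of 9 weeks are the exercise groups, so exercise and the title numbers cannot be told apart either. They differed in 2 genes with edgeR and 487 with DESeq2 (418 in the highest other DESeq2 split), and did not overlap for 557 genes (3.01%, 0.794% by chance).

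The hypothesis that long genes fall relative to short genes with age was met in both runs, with an unadjusted exact permutation p of 0.00794 in replicates 1 to 5 and 0.0159 in replicates 6 to 10 (n = 5 against 5 each). The second did not pass adjustment over 5 measures (0.0794). RNA quality may also move such a slope and was not measured in these files.

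Few genes were called with edgeR for exercise at 9 weeks. DESeq2 called 487, and among its 30 splits, added after the data were seen, 0 others gave as many (highest 418, median 7). The splits that follow are those of edgeR. Of 100 splits of the 10 fish, 4 gave 2 or more genes, the real one included, just under the share of 0.05 that was set, and with the fish-to-fish axis as a covariate 5 of 100 did, so chance is not firmly excluded for this count. One split gave 331 genes and another 31, which points to a structure of the samples. The first exchanges exercised replicate 1 with unexercised replicate 5, the fish whose scores on the fish-to-fish axis (0.873 and -0.765) lie with the other group. It gave 0 genes with the axis as a covariate. The second exchanges replicate 4 of each group, whose scores (-0.935 exercised and 0.773 unexercised) lie with their own groups. It gave 53 genes with the axis as a covariate, so the axis does not account for it. The prediction that this axis hides many calls was not met, but the test cannot decide it. Its mean score was 0.55 in unexercised and -0.54 in exercised fish, so the covariate can also take up part of the exercise contrast. With the axis as a covariate 2 genes were called, neither of them among the first 2, and the highest other split gave 53. The folds of the first 2 became somewhat smaller and their SE larger, which ended their calls: from 0.85 (SE 0.0973) to 0.73 (SE 0.106, adjusted p = 0.116) for Nfu_g_1_008319 and from -0.82 (SE 0.0862) to -0.75 (SE 0.104, adjusted p = 0.111) for Nfu_g_1_013151, in edgeR's test. Low power for small changes stays open, since 36% of simulated 2-fold and 82% of simulated 4-fold changes were called. No gene was called in edgeR's main test with a change of more than 2-fold. This does not show that such changes are absent in genes with a wide spread between fish.

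The fish-to-fish axis held 36.8% of the variance inside the 27-week runs. Its mean score was 0.55 in unexercised and -0.54 in exercised fish of 9 weeks (exact permutation p = 0.0714, n = 5 against 5), which did not pass.

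Both genes called for exercise differed between the 27-week runs, with replicates 1 to 5 lying on the side of the exercised fish. The hypothesis that the 2 contrasts point the same way was not supported and stays open. Over 16432 genes, which are not independent replicates, their correlation was 0.0272 (exact permutation p = 0.841 over the splits of the 9-week fish). With the fish-to-fish axis removed it was 0.0700, and the largest in size among the other splits was 0.286 (exact permutation p = 0.587). Of the 100 genes with the smallest exercise p, 60 had the same direction between the runs. Of these 100 genes, 40 were called between the runs, near the 41.6% called of all genes tested there. In 56 of 100 splits of the 9-week fish, the real one included, the genes with the smallest p leaned as far to either side, and the highest other had 89 of 100 on one side.

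The hypothesis that older fish differ more from each other was not borne out within title runs. The variance was larger at 27 weeks for 65.1% of genes, and 13 of 100 splits gave at least that share, the highest other being 73.3%. With the 27-week fish as 1 group, as first planned, the SD was larger for 81.4% of genes and 2 of 100 splits gave as much, a value that includes the difference between the runs.

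That the deposited RPKM table recycled the 20 library totals in row order was met in 100% of the genes checked, and in 0% with each library's own total.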
